A study of Schizosaccharomyces pombe with 29 samples.

How the data were processed

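Experiments of 3 kinds, all on 2-colour arrays, were analysed: ChIP of histone H3 acetylated at K9/K14 (8 arrays), RNA (9 arrays) and mononucleosomal DNA from micrococcal nuclease digestion (11 arrays with a scanner file, plus 1 sample used only through the deposited value table). Per the labels, Cy5 held the ChIP DNA, the mutant RNA or the mononucleosomal DNA, and Cy3 the whole cell extract, the wildtype RNA or the genomic DNA. No dyes were swapped, so a dye effect is not averaged out of any ratio. Groups follow the sample titles. Replicate numbers of the hrp1Δhrp3Δ and hrp3Δ RNA samples were given in accession order, and they follow the array design. Replicate 1 of both strains was of the design of the alp13Δ and set2Δ RNA arrays, and replicate 2 of that of the hrp1Δ RNA arrays. Replicate 2 of both strains also shared a slide with hrp1Δ replicate 1. Beyond this the numbers pair nothing.

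Scanner files were made with Agilent Feature Extraction, version 10.7.1.1 or 10.7.3.1 per the file headers and 10.7.3.1 per the submitters' processing notes. Per the file headers, the arrays were designed on a build named Spombe:NCBI:Feb2002. The reference genome at hand carries another build name, and it was used only to place the runs of lost input DNA by base composition. No unit or comparison rests on it. The deposited raw and background median signals and processed signals are intensity values per spot, the processed ones background-subtracted and dye-normalized by Feature Extraction as the statistics in these files show. The headers do not name the dye normalization method. The deposited log ratio is on the log10 scale, Cy5 over Cy3, per the file headers. The deposited value tables of the series hold log2 values for the first 65529 probes of each array design. Outside values set to 0, their columns equalled the scanner log ratio on the log2 scale within 0.001 for 100% of probes (r = 1), so scale and direction were settled and no centring had been applied. Column medians were 0 in all 9 RNA columns, -0.06, -0.06, -0.01, -0.00, 0.02, 0.03, 0.09 and 0.11 in the ChIP columns of wildtype, hrp1Δhrp3Δ, set2Δ and alp13Δ in that order, and 0.08, 0.10, 0.08, 0.06, 0.06, 0.03, 0.04, 0.06, 0.08, 0.07, 0.06 and 0.07 in the mapping columns of wildtype, hrp1Δhrp3Δ, pob3Δ, set2Δ, alp13Δ, mit1Δ, hrp1Δ and hrp3Δ. In the RNA columns, 18.8% to 32.2% of values were 0. Direction and centring of the set2Δ mapping column could not be set against a scanner file and stay unknown, and its scale was taken to be that of the other columns.

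RNA arrays were background-corrected with normexp (offset 50) on the median signals, because the files hold no mean signals, and loess-normalized within each array in limma 3.58.1 on R 4.3.3. Control spots and spots marked as outliers had weight 0 in loess and were left out of all values, and saturated spots were kept. ChIP and mapping arrays were used as log2 ratios of the processed signals, centred on each array's median, with no loess. Each RNA and ChIP array held 174063 tiling probes, and each mapping array 963673. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

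No column of the files gives a probe's sequence, gene or position, so the regions planned from gene annotation were replaced by regions defined on probe numbers. The first 146000 numbers of the RNA and ChIP designs, 73 of 87 blocks of 2000, gave strand-specific runs and were used. In this part 1832 units were found, and a unit's RNA value was the median over at least 3 probes of one strand. Promoter values were means over the 8 numbers before the 5′ end, and body values means from 12 numbers after the 5′ end to the 3′ end, in the 1592 units of at least 25 numbers. The numbering of the mapping design, 4 numbers for each of the other design, was matched through input DNA: in 24 of 24 blocks of 6000 probes the best match lay within 1 number, at r = 0.57 to 0.79. Nucleosome profiles were aligned on the minimum of the signal, averaged over the strains with a scanner file and then over 15 numbers, between 40 numbers before and 10 after the 5′ end. Amplitude was the SD of the profile over 10 to 100 numbers after the minimum, after subtracting a running mean of 15 numbers, and occupancy the mean within 10 numbers of the minimum.

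Before the data were examined, the samples in each fit, the tests, the threshold and most alternatives were fixed. The use of units in place of genes, all sizes given in probe numbers, the alignment on the depleted minimum and the median signals were chosen after the data were seen. The translation start as another alignment point, and tests of 17 gene lists fixed beforehand, needed gene names or coordinates and were not run. Lost input DNA was called where a running median over 5 probes lay more than 2 below the median of all arrays of the kind on the log2 scale, over at least 5 numbers. The run at probes 213517 to 213537, lost from most mapping arrays, was found through the ChIP design and measured against the wildtype mean.

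Differences per unit were tested with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment within each comparison and an adjusted p of 0.05 as threshold. RNA fits held the 8 arrays of the 4 strains with 2 arrays and tested each strain's mean ratio against 0. The ChIP fit held all 8 arrays, and the mapping fit the 7 arrays of wildtype, hrp1Δhrp3Δ and pob3Δ. Mean amplitudes were compared by an exact two-sided permutation test. Strains with 1 array are given as values. The units named are the highest and lowest changes among those past the threshold whose mutant arrays all lie on one side, a rule fixed beforehand, of which at most 1 in each direction is printed here. On simulated values with the residual SDs of the real units, 200 changed units and a change of 0.5 (log2), limma recovered 63.5% of the changed units for antisense RNA in hrp1Δhrp3Δ (1832 units), 96.5% for body acetylation (1592 units) and 68.5% for amplitude (1592 units). At a change of 1 it recovered 96.0%, 100% and 98.5%. Between 1.99% and 6.16% of the calls in these runs were of unchanged units. The unit finder recovered 100% of 200 planted units, and the amplitude measure gave a ratio of 0.50 for a planted wave of reduced height, as built.

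Alternatives covered the background correction, loess, the scaling of arrays, dim probes, the summary over probes, the slide and array design as blocks, the replicate number as a block, the deposited value tables, a 1.5-fold minimum, other windows and each array left out in turn. Those on the unit definition, the alignment and the centring were added after the data were seen.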

Results

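Fission yeast (Schizosaccharomyces pombe) cells in log phase in rich medium were profiled on 2-colour Agilent tiling arrays. The strains lacked hrp1, hrp3 or both, which encode the Chd1-type chromatin remodelers of this yeast, or lacked set2 (a histone methyltransferase that acts on transcribed genes), alp13 (a chromodomain subunit of a Clr6 histone deacetylase complex), pob3 (a subunit of the histone chaperone FACT) or mit1 (a remodeler of the SHREC complex). By its title, the study asked how the Chd1-type remodelers act on nucleosome organization and on cryptic transcription. Histone H3K9/K14 acetylation was measured by ChIP in 8 samples, 2 each of wildtype, hrp1Δhrp3Δ, set2Δ and alp13Δ, against the whole cell extract of the same strain. RNA was measured in 9 samples as mutant over wildtype, 2 each of hrp1Δhrp3Δ, hrp3Δ, hrp1Δ and alp13Δ and 1 of set2Δ. Nucleosomes were mapped in 12 samples as mononucleosomal DNA released by micrococcal nuclease over genomic DNA, with 3 wildtype, 2 hrp1Δhrp3Δ and 2 pob3Δ samples and 1 each of set2Δ, alp13Δ, mit1Δ, hrp1Δ and hrp3Δ. The series text gives 2 wildtype mapping samples, and the labels give 3. A scanner file was used for 28 of the 29 samples. The set2Δ mapping sample was used only through its column in the deposited value table. The series text calls the replicates biological. The limma p-values and the permutation test of amplitudes rest on the spread between such samples, which limma pools in part over units. The small number of arrays limits their precision. Permutation p-values of correlations across units do not measure that spread.

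The files number the tiling probes and do not pair the probes with genes or coordinates, so features are given by probe number and no gene is named for them. Odd and even numbers followed the 2 strands. On the wildtype RNA channel, probes 2 numbers apart correlated at r = 0.82 and adjacent probes at r = -0.34. In total, 1832 transcription units were defined as runs of at least 10 probes of one strand whose wildtype RNA exceeded that of the neighbouring probes of the other strand by at least 2 on the log2 scale. The units had a median of 21 probes and covered 62.3% of the densely tiled part of the arrays. Their 5′ ends were set by wildtype H3K9/K14 acetylation, which averaged 0.56 (log2 ChIP over input) at the lower-numbered and 0.00 at the higher-numbered end of the 928 odd units, and -0.01 and 0.58 at those ends of the 904 even units. Signals were strong for DNA. On every ChIP array more than 99.9% of probes were well above background in both channels, and on the mapping arrays 98.0% to 100.0%. In the RNA channels these shares were 65.2% to 80.0% for Cy5 and 64.8% to 71.3% for Cy3.

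Each strain checked lacked DNA or RNA over a run of probes that fits its label, except that 2 runs in mit1Δ leave its locus unsettled. At the run of probes 160355 to 160371, absent from the input DNA of both hrp1Δhrp3Δ ChIP samples (median log2 -5.55 against the median of all ChIP arrays), the RNA log2 ratio was -5.14 and -4.03 in hrp1Δhrp3Δ and -3.99 and -3.88 in hrp1Δ. At probes 173089 to 173104, absent from the same input (-6.51), the RNA ratio was -5.90 and -4.98 in hrp1Δhrp3Δ and -5.63 and -4.69 in hrp3Δ. Probes 157925 to 157929 were absent from alp13Δ input (-7.20), with RNA ratios of -6.23 and -6.12 in alp13Δ, and probes 173209 to 173218 were absent from set2Δ input (-6.57), with an RNA ratio of -4.76 in set2Δ. In strains that keep the locus, these RNA ratios lay between -0.44 and 0.60. Many of these probes were not well above background in the deletion strain, so the ratios there are bounds. On the mapping arrays, genomic DNA was lost over probes 920690 to 921101 in hrp1Δ and both hrp1Δhrp3Δ samples (-5.31), 962699 to 962715 in hrp3Δ and both hrp1Δhrp3Δ samples (-6.07), 318915 to 319075 in both pob3Δ samples (-5.70) and 859938 to 860044 in alp13Δ (-4.43). The mit1Δ sample lacked 2 runs, probes 100199 to 100616 (-3.17) and 467478 to 467655 (-3.52). A further run, probes 213517 to 213537 (-5.01), was lost from the hrp1Δ, hrp3Δ, hrp1Δhrp3Δ and pob3Δ mapping samples and kept in those of wildtype, alp13Δ and mit1Δ. The set2Δ mapping sample was not checked in this way. The alp13Δ and set2Δ RNA samples carry a strain characteristic that names hrp1Δ. Their RNA was lost at the alp13Δ and set2Δ runs and not at the hrp1Δ run, so their titles were followed.

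Nucleosome order inside units was weaker in hrp1Δhrp3Δ than in wildtype, and in pob3Δ the amplitude was lower on arrays not scaled to one SD. In wildtype, averaged over 1592 units of at least 25 numbers, nucleosome peaks followed the depleted region at the 5′ end at a spacing of 15 probe numbers, with peaks 44, 59, 74 and 89 numbers from its minimum in replicates 1 and 3. The amplitude of this wave was 0.110 ± 0.003 (SD, n = 3) in wildtype, 0.0814 ± 0.009 (n = 2) in hrp1Δhrp3Δ and 0.0868 ± 0.002 (n = 2) in pob3Δ, a change of -25.8% and -20.9%. Every hrp1Δhrp3Δ and pob3Δ array lay below every wildtype array. With all arrays scaled to the same SD this held in hrp1Δhrp3Δ only, as the pob3Δ amplitudes were then 0.0938 and 0.103 against 0.100 to 0.108 in wildtype. The loss was larger farther into the unit: in hrp1Δhrp3Δ the amplitude was 0.76 and 0.91 of the wildtype mean over 10 to 24 numbers from the minimum, lowest at 0.12 and 0.21 over 55 to 69 numbers, and 0.18 and 0.26 over 85 to 99 numbers. In pob3Δ the ratios over these windows were 0.86 and 0.84, 0.59 and 0.56, and 0.55 and 0.45.

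The hrp3Δ array resembled hrp1Δhrp3Δ, and the hrp1Δ array resembled wildtype. The hrp3Δ amplitude was 0.0801, and its ratio to wildtype went from 0.84 near the minimum to 0.34 at 55 to 69 and 0.27 at 85 to 99 numbers. The hrp1Δ amplitude was 0.115, with ratios between 1.00 and 1.07. Amplitudes of alp13Δ (0.110) and mit1Δ (0.109) lay within the wildtype range of 0.107 to 0.114. For set2Δ, the deposited value table covered 169 units, over which its amplitude was 0.117 against 0.111 to 0.114 in wildtype, on a scale that could not be set against a scanner file. These 5 strains had 1 array each, so their values have no replicate check and no test.

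**Figure D1:**
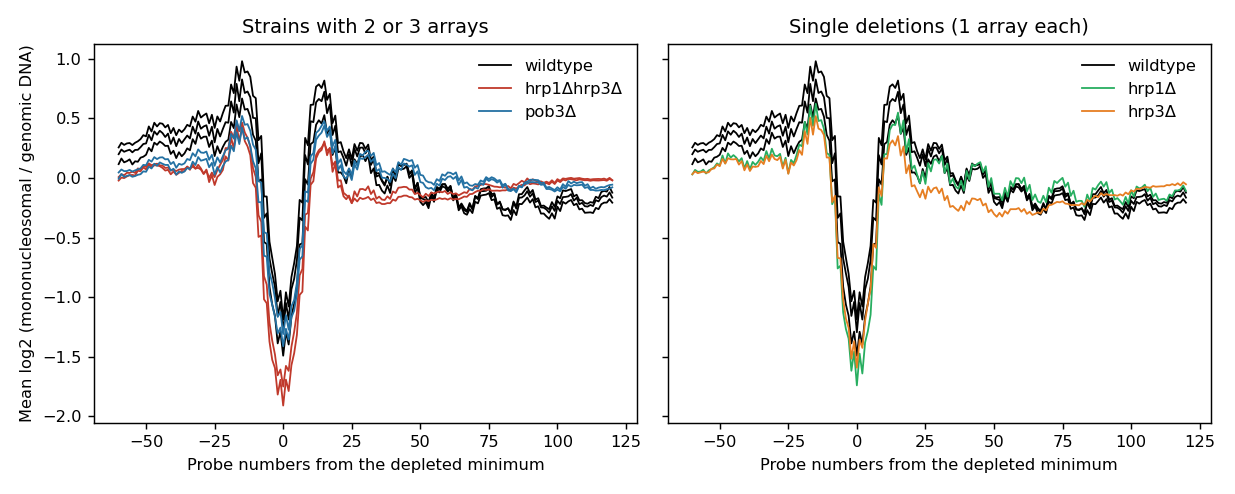
Mean log2 ratio of mononucleosomal over genomic DNA (vertical axis) against distance in probe numbers from the depleted minimum into the unit (horizontal axis), averaged over 1592 units, 1 line per array. Beyond the first nucleosome, the swing between peaks and troughs is smaller in hrp1Δhrp3Δ, pob3Δ and hrp3Δ than in wildtype and hrp1Δ, while the level about which it runs differs between arrays.

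Unit by unit, amplitude fell in 1109 and rose in 9 of 1592 units in hrp1Δhrp3Δ, with a median log2 change of -0.47, and fell in 689 and rose in 10 in pob3Δ, with a median of -0.30 (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05 in each call). The largest fall in hrp1Δhrp3Δ, -1.44 ± 0.15 (SE, limma adjusted p = 4.41e-19), was in the unit at probes 9959 to 9999, and the largest rise, 0.65 ± 0.15 (limma adjusted p = 4.33e-05), at probes 23816 to 23850. Both p-values lean on a spread pooled over all units, so they say little about the spread between the samples of 1 unit. The 2 hrp1Δhrp3Δ arrays differed over the units as a whole, with median changes of -0.62 and -0.32. The exact two-sided permutation test of the array amplitudes gave p = 0.1 for each of hrp1Δhrp3Δ and pob3Δ, which is the smallest that 10 splits of 5 arrays allow. Scaling every array to the same SD left the hrp1Δhrp3Δ change at -24.8% and brought that of pob3Δ to -5.11% (exact permutation p = 0.5) and its units to 125 higher and 278 lower, and normexp brought these to 71 higher and 325 lower. Aligned on the unit edge in place of the minimum, the mean amplitude changed by -61.6% in hrp1Δhrp3Δ and -29.4% in pob3Δ (exact permutation p = 0.1 for both, the smallest possible). Without replicate 1 of hrp1Δhrp3Δ 734 units were called, and for pob3Δ 123 without its replicate 2, 394 without wildtype replicate 3 and 244 with the replicate number as a block.

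**Figure D2:**
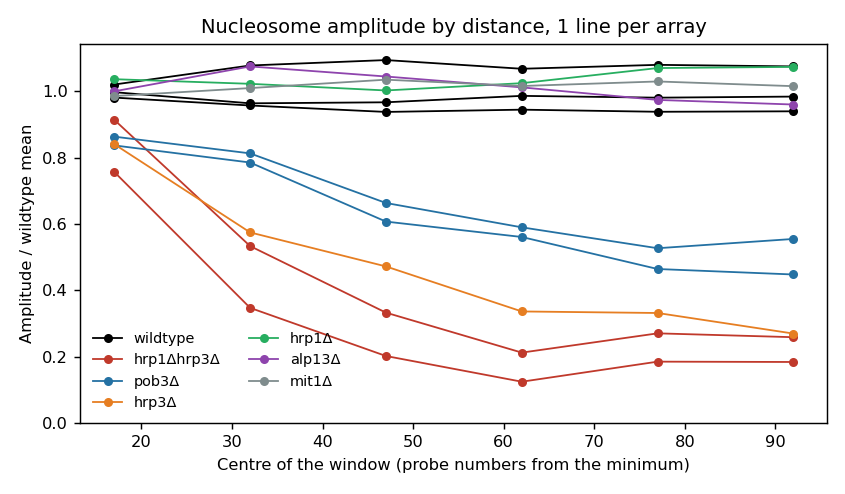
Nucleosome amplitude in 15-number windows, divided by the wildtype mean of the window (vertical axis), against the window's distance from the depleted minimum in probe numbers (horizontal axis), 1 line per array. In hrp1Δhrp3Δ the ratio is lowest at 55 to 69 numbers (0.12 and 0.21) and 0.18 and 0.26 at 85 to 99, in hrp3Δ it reaches 0.27 at 85 to 99, and in hrp1Δ it lies between 1.00 and 1.07.

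The depleted region at the 5′ end held less mononucleosomal DNA in hrp1Δhrp3Δ. Occupancy around the minimum fell in 1094 and rose in 8 of 1592 units, with a median log2 change of -0.56, and the array medians were -0.69 and -0.86 against -0.30, -0.17 and -0.44 in wildtype. In pob3Δ it fell in 29 and rose in 2 units, with a median change of -0.21 and array medians of -0.54 and -0.38. The array medians of the strains with 1 array were -0.55 in alp13Δ, -0.41 in mit1Δ, -0.59 in hrp1Δ and -0.51 in hrp3Δ. The median difference from the wildtype mean was below 0 on every mutant array, from -0.10 in mit1Δ to -0.65 in hrp1Δhrp3Δ replicate 2. A lower value is thus not particular to hrp1Δhrp3Δ. The minimum was placed on an average in which each strain counted alike and most were mutants, which can favour places where mutants are low. Calls are from limma with Benjamini-Hochberg adjustment. In pob3Δ the 31 calls depended on the settings, with 583 at equal SD, 587 with the replicate number as a block, 178 aligned on the unit edge and 141 with normexp. There 386 units passed at an unadjusted p of 0.05, and the adjusted count depended on single arrays, with 689 calls without wildtype replicate 3, 9 without wildtype replicate 1 and 0 without either pob3Δ replicate. In hrp1Δhrp3Δ 566 units were called without its replicate 2.

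RNA from the antisense strand of units rose widely in hrp1Δhrp3Δ. There it rose in 768 and fell in 182 of 1832 units, with a median log2 change of 0.20 over all units and array medians of 0.23 and 0.16. Single deletions changed fewer units: 238 rose and 14 fell in hrp3Δ (median 0.07), and 121 rose and 2 fell in hrp1Δ (median 0.02). In alp13Δ 1147 rose and 200 fell, with a median of 0.59 and array medians of 0.55 and 0.58. The 1 set2Δ array had a median of 0.19 and was not tested. The highest call in hrp1Δhrp3Δ was the unit at probes 42873 to 42921, at 3.22 ± 0.11 (SE, limma adjusted p = 3.16e-06), and the lowest was at probes 21707 to 21727, at -1.24 ± 0.14 (limma adjusted p = 3.57e-04). The highest call in alp13Δ was at probes 111039 to 111117, at 5.44 ± 0.39 (limma adjusted p = 8.61e-06).

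The antisense gain in hrp1Δhrp3Δ, hrp3Δ, alp13Δ and set2Δ lay inside units and was small or absent at their 3′ ends. With each unit divided into 5 segments from its 5′ end, the median antisense change on the first hrp1Δhrp3Δ array was 0.26, 0.29, 0.28, 0.19 and -0.05, and on the second 0.22, 0.22, 0.21, 0.13 and -0.01. In alp13Δ segment 2 had 0.77 and 0.76 on the 2 arrays and segment 5 had 0.08 on both. In set2Δ these segments had 0.28 and 0.02. In hrp3Δ segment 3 had 0.17 and 0.08 and segment 5 had 0.00 and -0.02. In hrp1Δ no segment exceeded 0.09. The median of the last minus the first segment was below 0 on every array, hrp1Δ included (-0.16 and -0.08). A lower value at the 3′ end is thus not particular to some strains.

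**Figure D3:**
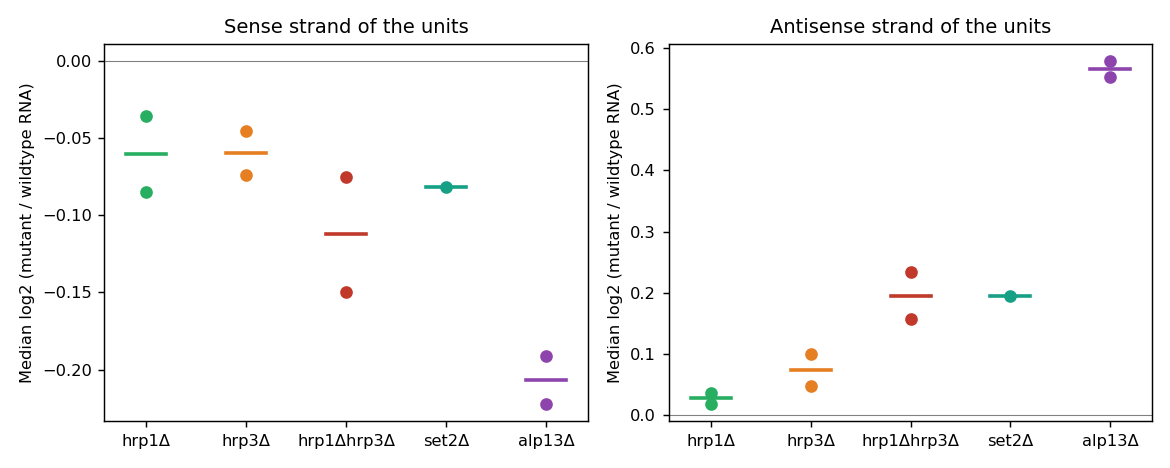
Median log2 ratio of mutant over wildtype RNA over 1832 units (vertical axis) for the sense strand (left) and the antisense strand (right), 1 point per array and a bar at the mean of the strain's arrays. Antisense medians range from 0.02 in hrp1Δ to 0.58 in alp13Δ, and sense medians lie between -0.22 and -0.04.

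The antisense calls come from limma fits of the mean log2 ratio against 0 with Benjamini-Hochberg adjustment. Both hrp1Δ arrays were of another array design than the alp13Δ and set2Δ arrays, while hrp1Δhrp3Δ and hrp3Δ each had an array of either design. Counts of hrp1Δ and alp13Δ are therefore not compared within a design. Each ratio is to the wildtype RNA on the same array, and if the arrays shared one wildtype RNA, which the labels do not say, the wildtype's own spread is left out. Without loess 1005 units were higher and 42 lower in hrp1Δhrp3Δ and 689 units were called in hrp3Δ, while centring each array on its median over units, which takes away any shift shared by the units, gave 587 higher and 481 lower in hrp1Δhrp3Δ and 740 higher and 686 lower in alp13Δ. Without its replicate 1, hrp1Δhrp3Δ had 547 calls. The count was 42 without replicate 1 and 137 without replicate 2 in hrp3Δ, and 38 without replicate 1 and 33 without replicate 2 in hrp1Δ.

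Antisense RNA was higher in hrp1Δhrp3Δ than in either single deletion. Against hrp1Δ, 446 units were higher and 92 lower, with a median difference of 0.14, and against hrp3Δ 186 were higher and 10 lower, with a median of 0.09 (limma, Benjamini-Hochberg adjustment). Replicate 1 of hrp1Δhrp3Δ and of hrp3Δ was of another array design than their replicate 2 and both hrp1Δ arrays. Antisense medians were higher on replicate 1 than on replicate 2, at 0.23 against 0.16 in hrp1Δhrp3Δ and 0.10 against 0.05 in hrp3Δ. The difference from hrp1Δ over all arrays may thus hold a design effect. One slide, of one design, held an array of all 3 strains, and on it the median differences were 0.13 and 0.10, with 64.4% and 66.2% of units above 0. With the slide as a random block, 305 units differed from hrp3Δ, and with the array design as a block 304. Centring each array on its median over units gave 319 higher and 179 lower against hrp1Δ, and leaving out loess 605 higher and 35 lower. The count against hrp1Δ was 146 without hrp1Δ replicate 1, 181 without hrp1Δ replicate 2 and 273 without hrp1Δhrp3Δ replicate 1. That against hrp3Δ was 13 without hrp3Δ replicate 1, 16 without hrp3Δ replicate 2, 66 without hrp1Δhrp3Δ replicate 1 and 523 without hrp1Δhrp3Δ replicate 2.

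Units with more antisense RNA overlapped between strains. Of the 768 in hrp1Δhrp3Δ, 220 were also higher in hrp3Δ (99.8 for independent lists of those sizes), 81 in hrp1Δ (50.7) and 703 in alp13Δ (481). The expected values are the product of the list sizes over the 1832 units tested. The labels do not say whether arrays shared one wildtype RNA, so part of the excess may come from it.

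Sense RNA changed in fewer units than antisense RNA in hrp1Δhrp3Δ, hrp3Δ and alp13Δ, and in more in hrp1Δ. Without loess this turned in hrp3Δ, with 768 sense and 689 antisense calls. In hrp1Δhrp3Δ 84 units rose and 198 fell, in hrp3Δ 28 rose and 43 fell, in hrp1Δ 191 rose and 210 fell and in alp13Δ 148 rose and 478 fell, with median log2 changes of -0.11, -0.06, -0.06 and -0.21. One unit, at probes 133430 to 133550, led the rises in both hrp1Δ (5.12 ± 0.18, SE, limma adjusted p = 2.29e-08) and alp13Δ (4.49 ± 0.18, limma adjusted p = 8.91e-08). In hrp1Δhrp3Δ the highest call was at probes 5557 to 5587 (3.91 ± 0.80, limma adjusted p = 0.0125) and the lowest at probes 13950 to 13970 (-1.73 ± 0.24, limma adjusted p = 0.00196). Of the units that rose in hrp1Δhrp3Δ, 43 also rose in alp13Δ (6.79 for independent lists) and 38 in hrp1Δ (8.76). These lists are linked in the same ways as the antisense lists. On the set2Δ array the sense median was -0.08. Units were chosen by high sense RNA in wildtype, which is the denominator of these ratios, and this can favour lower sense ratios.

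Sense loss in alp13Δ was greatest at the 5′ end, with medians of -0.42 and -0.38 in segment 1 and -0.15 and -0.11 in segment 5. In set2Δ these were -0.19 and 0.00. In hrp1Δhrp3Δ they were -0.18 and -0.01 on one array and -0.07 and -0.04 on the other.

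The balance of sense calls differed with and without loess. With each array centred on its median over units, which sets that median to 0 by construction, calls were 131 higher and 124 lower in hrp1Δhrp3Δ, 240 higher and 164 lower in hrp1Δ and 241 higher and 191 lower in alp13Δ, and without loess 63 higher and 674 lower, 120 higher and 548 lower and 119 higher and 855 lower. Without loess hrp3Δ had 38 higher and 730 lower, and alp13Δ on the scanner's processed signals 171 higher and 256 lower. Counts without replicate 1 and without replicate 2 were 22 and 123 in hrp1Δhrp3Δ, 21 and 118 in hrp3Δ, 106 and 175 in hrp1Δ and 168 and 259 in alp13Δ. More were then higher than lower without replicate 1 in hrp1Δhrp3Δ (13 and 9) and hrp3Δ (16 and 5) and without replicate 1 (64 and 42) or 2 (116 and 59) in hrp1Δ. At a minimum of 1.5-fold, hrp1Δ had 144 higher and 124 lower.

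The H3K9/K14 acetylation signal at the 5′ ends of units, as ChIP over input, was lower relative to the rest of the genome in all 3 mutants. In wildtype the medians over 1832 promoters were 0.60 and 0.73 (log2 ChIP over input, centred on each array's median). They were 0.35 and 0.41 in hrp1Δhrp3Δ, 0.27 and 0.26 in set2Δ and -0.15 and -0.16 in alp13Δ. Acetylation fell at 1213 and rose at 39 promoters in hrp1Δhrp3Δ, fell at 1575 and rose at 40 in set2Δ, and fell at 1739 and rose at 42 in alp13Δ, with median changes of -0.30, -0.47 and -0.88. The deepest fall in alp13Δ was -1.89 ± 0.08 (SE, limma adjusted p = 5.04e-09), at the unit of probes 120957 to 121061, and in hrp1Δhrp3Δ -1.41 ± 0.09 (limma adjusted p = 3.69e-07), at that of probes 118323 to 118393.

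**Figure D4:**
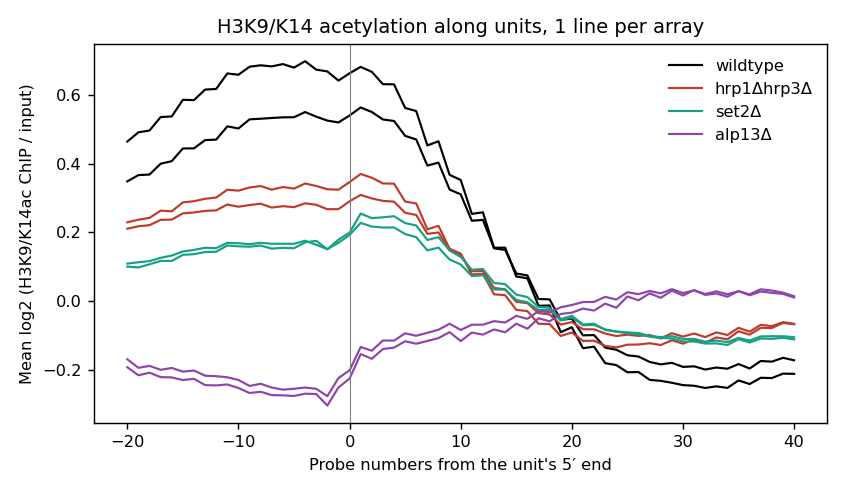
Mean log2 ratio of H3K9/K14 acetylation ChIP over input (vertical axis) against distance in probe numbers from the 5′ end of the unit (horizontal axis; positive values lie inside the unit), 1 line per array. Wildtype promoters are the highest and alp13Δ promoters the lowest, and the order of these 2 strains turns inside the unit.

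Inside units, median acetylation was higher than in wildtype in all 3 mutants. Body acetylation had medians of -0.14 and -0.20 in wildtype, -0.05 and -0.07 in hrp1Δhrp3Δ, -0.04 and -0.03 in set2Δ and 0.13 and 0.13 in alp13Δ, over 1592 units. It rose in 629 and fell in 259 units in hrp1Δhrp3Δ, rose in 592 and fell in 351 in set2Δ, and rose in 893 and fell in 415 in alp13Δ, with median changes of 0.08, 0.05 and 0.22. The highest calls were 1.37 ± 0.09 (SE, limma adjusted p = 4.04e-06) at probes 16793 to 16819 in hrp1Δhrp3Δ, 1.13 ± 0.07 (limma adjusted p = 7.13e-07) at probes 95378 to 95408 in set2Δ and 1.22 ± 0.06 (limma adjusted p = 3.25e-07) at probes 133678 to 133754 in alp13Δ.

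Each ChIP slide held 1 array of every strain. Within slides 1 and 2, the median promoter differences from wildtype were -0.26 and -0.35 in hrp1Δhrp3Δ, -0.39 and -0.54 in set2Δ and -0.80 and -0.97 in alp13Δ. The median body differences were 0.07 and 0.10, 0.02 and 0.07, and 0.19 and 0.23. Calls are from limma with Benjamini-Hochberg adjustment over all 8 ChIP arrays. A ratio within an array shows unequal change between regions, and a change of acetylation shared by the whole genome is not measured. The ratio is to whole cell extract and not to histone H3, so fewer nucleosomes in a region would also lower it. Around the depleted minimum, the median occupancy difference from the wildtype mean was -0.47 and -0.65 in hrp1Δhrp3Δ and -0.33 on the alp13Δ array. Less acetylation per nucleosome and fewer nucleosomes at promoters were not told apart. Without its replicate 1, hrp1Δhrp3Δ had 791 promoter calls, against 1252 with both, and with the deposited value table, which covers 734 of the bodies, the body calls were 331 higher and 103 lower in set2Δ and 488 higher and 118 lower in alp13Δ.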

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

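The tests of dim probes, of the choice of units, of the dye, of dynamic range and of the strain background were chosen only after the results they concern were seen.

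Input DNA was lost or low over several runs of probes that the labels leave wholly or partly unaccounted for. Values are log2 against the median of all arrays of the kind, and against the wildtype mean for the run that most mapping arrays lack. Probes 53380 to 53385 were absent from the input of both hrp1Δhrp3Δ ChIP samples (-7.35, against -0.38 to 0.59 in the others). Probes 213517 to 213537, at the matching place of the mapping design, were absent from the hrp1Δ, hrp3Δ, hrp1Δhrp3Δ and pob3Δ samples (-5.01 over 6 arrays, against -0.08 to 0.03 in the others). In mit1Δ 2 runs were lost, probes 100199 to 100616 (-3.17) and 467478 to 467655 (-3.52), of which at most 1 can be the deleted locus of the label. In ChIP input, probes 40984 to 41215 (-2.01) and 141426 to 141592 (-1.83) were low in replicate 1 of alp13Δ and hrp1Δhrp3Δ. Probes 141343 to 141360 (-2.18) and 166643 to 166678 (-2.09) were low in replicate 1 of hrp1Δhrp3Δ. These 4 stretches were low and not lost, and they split by slide in every strain, wildtype included: over probes 40984 to 41215 the 4 arrays of slide 1 lay between -2.16 and -1.27 and the 4 of slide 2 between 1.27 and 1.76.

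Nucleosome amplitude was lower in hrp1Δhrp3Δ than in wildtype. A lower dynamic range of the arrays is argued against, since after scaling to one SD the higher hrp1Δhrp3Δ amplitude was 0.0796 and the lowest of wildtype 0.100. One factor on the whole profile would leave the ratio to wildtype equal along the unit, and its far window held 0.232 and 0.164 of the ratio in the near window. The ratio was thus not equal, although the near window adjoins a minimum chosen on these same arrays. Whether a different degree of digestion acts as one factor was not measured, so digestion stays open. A strain background that lacks probes 213517 to 213537 cannot be told apart from the deletions, because the 1 array that lacks the run and keeps both hrp3 and pob3, hrp1Δ, has no replicate, although its amplitude was 0.115 and the lowest of wildtype 0.107. Loss of the remodelers stays open beside this background and digestion.

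Antisense RNA was higher in hrp1Δhrp3Δ. Noise of dim probes is argued against, since leaving them out gave 792 higher units, against 768 with them. A dye bias shared by all arrays cancels in the difference from hrp1Δ, whose median was 0.139, and 0.131 on the shared slide. A choice of units by low antisense level in wildtype was tested only in part. Units chosen on the mean of both channels gave 671 higher, but that mean still holds the wildtype signal, so the test cannot exclude it. Loss of both remodelers stays open beside a part played by the choice of units.

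Promoter acetylation was lower and body acetylation higher in set2Δ and alp13Δ. Weaker ChIP enrichment, which compresses all ratios, would change promoters and bodies of one wildtype level alike. At wildtype levels between -0.25 and 0.25, the median promoter change lay below the median body change by 0.454 at the least (set2Δ, replicate 1) and by 1.11 at the most (alp13Δ, replicate 2). In hrp1Δhrp3Δ the difference was -0.33 and -0.39. A change of the deacetylation of unit bodies in these strains could lie behind the gain there and was not tested. Lower nucleosome occupancy at promoters, which a ratio to whole cell extract does not separate from acetylation, was not tested either.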

How the results depend on the processing

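The centring over units, the unit-edge alignment and the settings on the choice of units (strand difference, both channels, no unit on the opposite strand) were chosen after seeing the data. Leave-one-out fits aside, counts stayed within 1.5 times with the same direction, or mean amplitude differences kept their sign, in 135 comparisons under planned and 61 under added settings. Size and test of the mean amplitude differences were not compared, so pob3Δ at equal SD (-5.11%, exact permutation p = 0.5) is among the 135. They moved further in 44 and 6, and the prevailing direction reversed in 1 and 3. Except where a construction is named, the cause was not tested. The alignment on translation starts, the filter on annotated features of the opposite strand and the tests of gene lists were not run, because the files pair no probe with a gene.

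With the deposited value tables, fewer units are tested (827 for RNA, 828 promoters, 734 bodies, 169 for nucleosomes). Sense calls were 321 in alp13Δ, 169 in hrp1Δ, 134 in hrp1Δhrp3Δ and 32 in hrp3Δ, and antisense calls 487, 30, 237 and 76. The antisense differences of hrp1Δhrp3Δ had 142 calls against hrp1Δ and 53 against hrp3Δ. Promoter calls were 770 in alp13Δ, 458 in hrp1Δhrp3Δ and 663 in set2Δ, and body calls 606, 419 and 434. Amplitude calls were 100 in hrp1Δhrp3Δ and 59 in pob3Δ, and occupancy calls 109 in hrp1Δhrp3Δ. Without units that face another unit, 1068 remain. Antisense calls were then 779 in alp13Δ, 539 in hrp1Δhrp3Δ and 158 in hrp3Δ, and the differences had 305 against hrp1Δ and 123 against hrp3Δ.

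A minimum of 1.5-fold, by construction, lowers counts: antisense 569 in hrp1Δhrp3Δ, sense 386 in alp13Δ and 268 in hrp1Δ (144 higher and 124 lower, reversed against 191 and 210), promoters 167 in hrp1Δhrp3Δ and 519 in set2Δ, bodies 419 in alp13Δ, 100 in hrp1Δhrp3Δ and 126 in set2Δ, amplitude 562 in hrp1Δhrp3Δ and 190 in pob3Δ. Centring each array on its median over units reversed the balance of sense calls, by taking the median shift away: 432 in alp13Δ (241 higher), 404 in hrp1Δ (240 higher) and 255 in hrp1Δhrp3Δ (131 higher). With normexp and no loess, sense calls were 974 in alp13Δ, 668 in hrp1Δ, 737 in hrp1Δhrp3Δ and 768 in hrp3Δ, and antisense calls in hrp3Δ 689. On processed signals the difference from hrp3Δ had 323 calls. The mean over probes gave 203 antisense calls in hrp1Δ. The array design as a block gave 304 calls for the difference from hrp3Δ and 140 sense calls in hrp3Δ, and the slide as a random block 305 for the former. In pob3Δ, amplitude calls were 403 with equal SD and 396 with normexp, against 699, and occupancy calls 583 with equal SD, 141 with normexp and 178 aligned on the unit edge, against 31.

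With the replicate number as a block (replicate block), pob3Δ had 244 amplitude and 587 occupancy calls, and no other count moved by over 1.5 times: promoter calls were 1786 in alp13Δ, 1301 in hrp1Δhrp3Δ and 1629 in set2Δ, and body calls 1314, 926 and 968. Deviations of same-numbered samples correlated between -0.21 and 0.41 in ChIP and between -0.17 and 0.17 in mapping, and not every pair lay above 0.1. The numbers were therefore not taken to pair the samples, although in ChIP the number is also the slide, within which the report gives the differences. For RNA, the replicates of hrp1Δhrp3Δ and hrp3Δ carry no number in their labels, so no analysis was paired by labelled number. The numbers given to these 2 strains follow the array design, and the fit with that design as a block is reported above. The fit with the slide as a random block had a consensus correlation of 0.54 for sense and 0.516 for antisense values.

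Leaving out each array in turn, with limma's pooled spread and a lone sample taken to vary like the other groups, gave these ranges. Sense: 168 to 259 in alp13Δ, 106 to 175 in hrp1Δ, 22 to 123 in hrp1Δhrp3Δ, 21 to 118 in hrp3Δ. Antisense: 1141 to 1306, 33 to 38, 547 to 1010 and 42 to 137. Differences: 146 to 773 from hrp1Δ and 13 to 523 from hrp3Δ. Promoters: 1757 to 1785 in alp13Δ, 791 to 1456 in hrp1Δhrp3Δ, 1439 to 1675 in set2Δ. Bodies: 1216 to 1305, 697 to 946 and 719 to 952. Amplitude: 734 to 1315 in hrp1Δhrp3Δ and 123 to 677 in pob3Δ. Occupancy: 566 to 1293 and 0 to 689, where limma gave 386 at an unadjusted p of 0.05 with all arrays. Mean amplitude differences from wildtype: -0.0347 to -0.0219 and -0.0247 to -0.0211.

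Signal over background was lowest in RNA. Cy5 was well above background at 65.2% to 80.0% of probes on RNA arrays and at 99.8% or more on ChIP and mapping arrays, and repeated probes had a median SD of 0.13 to 0.16 on RNA arrays and of 0.03 to 0.06 on the others.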

Other observations

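The comparisons by expression level and length, the placing of lost runs on a genome and the alignment on the depleted minimum were tests chosen only after the results were seen, and the relations of antisense RNA to amplitude and acetylation and the sense values along units were planned before theirs.

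Weakly expressed units gained the most antisense RNA in alp13Δ, hrp1Δhrp3Δ and set2Δ. With the 1832 units divided by wildtype sense level into lowest, middle and highest groups of 611, 610 and 611, the median antisense change of the lowest group was 1.01 and 1.12 on the alp13Δ arrays, 0.56 and 0.28 in hrp1Δhrp3Δ and 0.42 in set2Δ. In the highest group it was 0.12 and -0.01, -0.14 and 0.03, and -0.04. Spearman correlations with the level were -0.407 and -0.497 in alp13Δ, -0.467 and -0.262 in hrp1Δhrp3Δ, -0.393 in set2Δ, -0.148 and -0.129 in hrp3Δ and -0.112 and 0.0042 in hrp1Δ. The level comes from the wildtype channel that is also the denominator of the ratios. By length, antisense RNA in alp13Δ went from 0.24 on both arrays in the shortest group to 0.88 and 1.01 in the longest.

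Body acetylation gains were larger in the longest than in the shortest units in all 3 strains, and larger in weakly than in highly expressed units in alp13Δ and set2Δ. In the group of lowest level it changed by 0.33 and 0.32 in alp13Δ and by 0.14 and 0.15 in set2Δ, and in the highest by -0.02 and -0.04 and by -0.07 and -0.08. In hrp1Δhrp3Δ the highest group had 0.12 and 0.08 and the lowest 0.06 on both arrays. By length, alp13Δ bodies went from 0.02 on both arrays to 0.44 and 0.43, and those of set2Δ from 0.02 and 0.03 to 0.05 and 0.07. Those of hrp1Δhrp3Δ went from 0.04 and 0.03 to 0.13 and 0.10. Every body window started 12 numbers after the 5′ end, where mean acetylation in alp13Δ was still below wildtype (-0.07 and -0.10 against 0.24 and 0.26). At that number set2Δ and hrp1Δhrp3Δ lay below wildtype too. Shorter units hold a larger share of this stretch, so the trend with length may come in part from the window. Nucleosome amplitude fell by similar amounts in all these groups in hrp1Δhrp3Δ, with medians of -0.59 to -0.65 in replicate 1 and -0.28 to -0.33 in replicate 2. In pob3Δ the peaks farther into the unit lay 61, 76 and 91 numbers from the minimum on both arrays, against 59, 74 and 89 in wildtype.

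If lost nucleosome order let antisense RNA start, units that lost more amplitude in hrp1Δhrp3Δ might gain more of it. The Spearman correlation over 1592 units was -0.0913 (permutation p = 3.20e-04), and the rule set beforehand asked for -0.1 or below. By that rule the prediction was not met, although the value lay near the bound. If body acetylation and antisense RNA rise together, gains of both should correlate. Over the same units the correlation was 0.417 (permutation p = 1e-05, the smallest that the permutations can give). Both permutation p-values treat units as independent and do not measure the spread between samples. RNA and chromatin came from different arrays, and the test does not say which change came first or whether a property of the units drives both.

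Starts inside units could also raise sense RNA toward the 3′ end. The sense change of the last minus the first segment had medians of 0.15 and 0.0172 on the hrp1Δhrp3Δ arrays and of -0.03 and 0.0423 on those of hrp1Δ. The rule set beforehand asked both hrp1Δhrp3Δ arrays to lie above both hrp1Δ arrays. That was not met, since 0.0172 lies below 0.0423. The hrp1Δhrp3Δ arrays differ by more than the gap between strains, which limits this test. In alp13Δ the medians were 0.21 and 0.22 and in set2Δ 0.16.

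As a hypothesis, it may be that the probe numbers follow the order of the reference genome. A free search that matched base composition to signal placed 7 of 11 lost runs on the gene named by the strain label. Of the 4 others, 2 had no labelled gene to land on (probes 53380 to 53385, and 1 of the mit1Δ runs, since at most 1 can be the deleted locus). Of the mit1Δ runs, the search placed probes 100199 to 100616 on the labelled gene and not probes 467478 to 467655. The placing missed 2 labelled runs and the files pair no probe with a gene, so none is given a gene or coordinate here.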
